A study of Mus musculus with 5 samples.

How the data were processed

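ZFP24 ChIP-seq was done with an antibody against ZNF24 on wild-type and Zfp24-null mouse cells from postnatal day 7, per the labels' protocols, and libraries were read as 75 nt single-end reads. The 5 libraries were assigned to groups from the submitters' descriptions, with 1 library in each of wild-type OPC, null OPC, wild-type OLG, null OLG and pooled input. The deposited files were 2 peak lists with 4 columns each, chromosome, start, end and a name, and no score, fold or tag count. Per the submitters' processing notes, BWA (version not given), HOMER 4.8.3 and the mm10 build were used. The peak-calling options, the threshold and how the null and input libraries entered the calling are not given in the sources used here. All OPC peaks were 209 bp wide and all OLG peaks 221 bp, as the deposited lists show. Library depth is unknown because the lists hold no read counts, and no interval that needs depth is given. A list made by a caller depends on depth and threshold, so that a deeper or cleaner library gives more peaks from the same binding.

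Coordinates were compared with GRCm38.p6 and the GENCODE M21 basic annotation, where the lengths of 20 of 20 chromosomes were equal and 0 peaks ran past a chromosome end. Positions are 1-based. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A promoter peak had its centre within 1 kb of a protein-coding transcript start. A repeat peak held at least 12 bases of tandem TCAT, on either strand and in any phase, in the 200 bp around its centre, and flanks were windows of the same width 2 kb to each side. Lists were compared by overlap of at least 1 bp, with OLG peaks moved 1000 times to random positions on their chromosome outside assembly gaps. Promoter shares were compared with 1000 random placements, repeats with the exact McNemar test, and gene lists and peak classes with Fisher's exact test, all two-sided except the overlap. Gene list p-values were adjusted by the Benjamini-Hochberg method over 28 tests, 14 lists in 2 cell types, with a threshold of 0.05. Of 438 listed genes, 434 were matched to the annotation. The steps were tested on simulated data. With 100 sites planted in both lists of the overlap comparison (4643 peaks), 103 overlapping peaks were found, against 4 with none planted. For the repeat share, 200 of 200 planted repeats were found, and for the gene list tests, run on 21728 simulated genes where the tests themselves used 21644, 4 of 200 random lists had p under 0.05.

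The tests, the gene lists, the rule for named genes and the first set of other settings were set before the data were examined. The rule named, for each list and cell type, all members with a peak within 10 kb or the 4 nearest, and Zfp24, Mbp, Mog, Cnp, Pdgfra, Cspg4, Olig1, Olig2, Sox10 and Myrf in any case. Some genes that the rule names are not reported here. It also asked for the 10 peaks with the highest deposited value, the 10 shared peaks with the highest mean rank, and failing a value the widest peaks. These parts were void, since the lists hold no value and all peaks of a list have equal width. The settings meant to keep the upper part of each list by peak value, and the strata by peak value, had no value to use either. The number in the peak name took its place, ranked within the chromosome, as an alternative chosen after seeing the data. Names in HOMER style carry such a number, but its meaning is not stated. Sorted by it, 93.0% of neighbouring OPC peaks and 90.2% of neighbouring OLG peaks lay further along the chromosome, which leaves it a coarse order at best. Other alternatives were other windows, repeat lengths, flanks and overlap rules, random lists matched on gene length, and, added later, matching on GC content and moving peaks within their class. Signal in the null and input libraries was not analysed here, so the background at each peak was not measured.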

Results

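Chromatin immunoprecipitation sequencing (ChIP-seq) was used to map where ZFP24, a zinc finger transcription factor also called ZFP191, sits in the genome of mouse oligodendrocyte progenitor cells (OPC) and of the oligodendrocytes (OLG) that arise from them. Oligodendrocytes are the myelin-forming glia of the central nervous system. The cells were isolated by immunopanning, and the OLG had been kept for 5 days without PDGF and with triiodothyronine at 40 ng/ml. The series held 5 libraries, namely wild-type OPC, Zfp24-null OPC, wild-type OLG, Zfp24-null OLG and a pooled input, with 1 library per group. Null cells and input were the controls of the experiment, and the values analysed here were 2 lists of peak positions, 1 for OPC and 1 for OLG. There were no replicates, so each test below compares the lists and not replicated conditions. The lists held no tag counts or scores, so the depth of each library is unknown, and the exact (Clopper-Pearson) 95% intervals cover counting error over peaks only.

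The OPC list held 4643 peaks and the OLG list 1752 peaks, a ratio of 2.65. Introns of protein-coding genes held 45.8% of OPC peak centres (95% interval 44.3 to 47.2) and 43.4% of OLG peak centres (41.1 to 45.8). Intergenic sequence held 29.5% of the OPC peaks and 22.9% of the OLG peaks. Coding exons held 7.90% and 14.4%, and 5' untranslated regions 8.31% and 11.8%, in the same order. The median GC content of the 200 bp around the peak centre was 51.5% in OPC and 59% in OLG, against 45.5% and 46% in windows 2 kb to the right. The number of peaks in a list depends on library depth and on the calling as well as on binding, and it has no replicate check.

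Promoters were a main location of ZFP24 peaks in both cell types. In OPC, 1646 peaks, or 35.5% (34.1 to 36.8), had their centre within 1 kb of the start of a protein-coding transcript, and in OLG 838 peaks, or 47.8% (45.5 to 50.2). Promoter peaks of OPC included those at Notch2, a receptor of the Notch pathway, 29 bp from its start site, and at the cell cycle kinase gene Cdk1, 70 bp away. Promoter peaks of OLG included those at Fgfr1, a fibroblast growth factor receptor gene, at 205 bp and at Vegfa, an angiogenic growth factor gene, at 132 bp. The same numbers of peaks placed at random on their chromosomes gave mean shares of 2.21% for OPC and 2.26% for OLG, so that the observed shares were 16-fold and 21.2-fold higher. The two-sided permutation p was 0.00200 for each list, the smallest that 1000 draws can give. Against positions matched on GC content, a comparison added after seeing the data, the ratios were lower, at 2.33 in OPC and 1.70 in OLG, with matched means of 15.2% and 28.1% and the same smallest p.

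Tandem TCAT repeats, a sequence that ZFP24 is known to bind, lay at many peaks of both cell types and at almost none of the flanks. A stretch of at least 12 bases of the repeat was found in 567 OPC peaks, or 12.2% (11.3 to 13.2), against a mean of 0.151% of the flanking windows. In OLG it was found in 100 peaks, or 5.71% (4.67 to 6.90), against 0.0571% of flanks. The median distance from the tract to the peak centre was 34 bp in OPC and 37.5 bp in OLG, against means of 48.9 bp and 48.8 bp for windows moved at random that still held the tract (one-sided permutation p = 0.000999, the smallest the draws can give, and 0.0170). This comparison was added after seeing the data. In the exact McNemar test against the right flank, 566 OPC peaks held the repeat where their flank did not and 6 flanks held it where their peak did not (two-sided p = 6.20e-159). For OLG the numbers were 100 and 0 (exact p = 1.58e-30).

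In OPC, TCAT stood apart from most other tandem tetranucleotides. Of 33 classes of repeat unit, counted over both strands and all phases, 2 were in more OPC peaks than flanks after Benjamini-Hochberg adjustment of the exact McNemar test, namely TCAT and the class of TCAC, which was in 43 peaks against 2 flanks (adjusted p = 9.72e-10). In the same test 6 classes were in fewer OPC peaks than flanks. In OLG, 1 class was higher, the TCAT class, and 1 was lower. The genome (chromosomes 1 to 19 and X) held 16888 TCAT tracts of 12 bases or more, of which 702 lay within 100 bp of an OPC peak centre, 121 of an OLG peak centre and 81 of both. The share of tracts at an OPC peak was 1.70% (1.46 to 1.97) for tracts of 12 to 15 bases, 7.72% (6.66 to 8.90) for 24 to 31 bases, 17.4% (15.3 to 19.7) for 32 to 47 bases and 42.1% (30.9 to 54.0) for the 76 tracts of 48 bases or more. For OLG peaks the corresponding shares were 0.358%, 1.41%, 1.90% and 10.5% (4.66 to 19.7). Among tracts of at least 16 bases, 8.04% of TCAT tracts were at an OPC peak, against 2.17% of the next class, AACG, where 3 of 138 tracts were. The TCAC class had 23 of 1129 tracts at an OPC peak, or 2.04% (1.30 to 3.04). In OLG the shares of TCAT and AACG, 1.28% (1.03 to 1.59) and 0.725% (0.0183 to 3.97), overlapped in their intervals, as did those of other classes with few tracts. Classes with many more tracts lay below TCAT in OLG, such as TCAC at 0.177% (0.0215 to 0.638) and AAAC at 0.00616% (0.00200 to 0.0144).

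**Figure D1:**
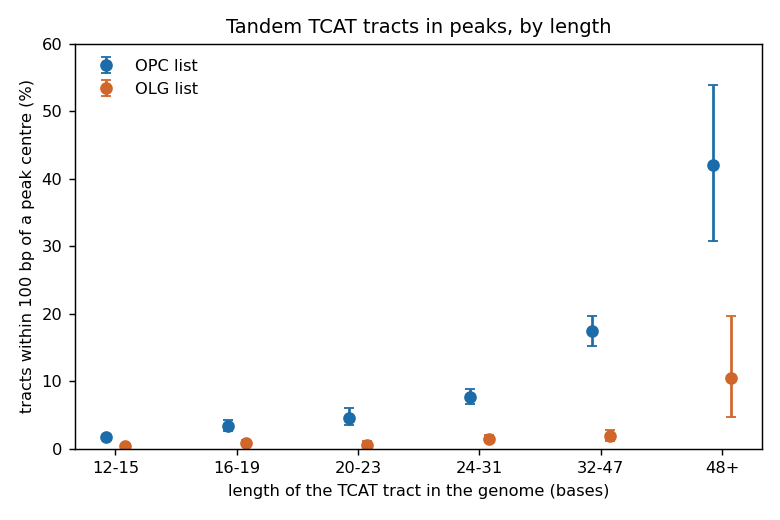
Share of genomic TCAT tracts within 100 bp of a peak centre (vertical axis, %) by tract length in bases (horizontal axis), for the OPC and the OLG list, with exact 95% intervals as bars. The OPC share runs from 1.70% at 12 to 15 bases to 42.1% at 48 bases or more, and the OLG share from 0.358% to 10.5%.

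The comparison of progenitors with differentiated cells asked whether ZFP24 sits at the same places in both. Only 254 peaks of each list overlapped by 1 bp or more, which was 5.47% (4.83 to 6.16) of OPC peaks and 14.5% (12.9 to 16.2) of OLG peaks. Shared sites lay at Zeb2, a transcription factor gene needed for myelination, at Cers2, a ceramide synthase gene, at Pik3r1, a regulatory subunit gene of PI3 kinase, and at Rock1, a cytoskeletal kinase gene. They also lay at Nefl, a gene of the neuronal marker list, and at Eef1a1, a gene of the ribosomal and housekeeping list. OLG peaks moved to random positions on their chromosomes met a mean of 1.43 OPC peaks and at most 7 in 1000 draws, so the overlap was 177-fold above chance (one-sided permutation p = 0.000999, the smallest the draws can give). With OLG promoter peaks moved to other promoters and repeat peaks to other TCAT tracts, an alternative chosen after seeing the data, the mean was 27.7 and the excess 9.16-fold. These moves did not match tracts on length or promoters on GC content. Tracts of 12 to 15 bases lay at an OPC peak in 1.70% of cases and those of 48 bases or more in 42.1%. The 9.16-fold excess is therefore not corrected for tract length or promoter GC content. The pooled input was a control of both cell types, and its part in the excess was not measured. Across the 254 shared pairs, which are not independent replicates, the number in the peak name, ranked within its chromosome, was correlated between the lists (Spearman's rho = 0.638, Pearson's r = 0.406, permutation p = 1e-05, the smallest that 100000 permutations can give). What that number stands for is not given in the sources used here. It partly follows position, which shared peaks have in common (rho with position 0.128 over OPC and 0.210 over OLG peaks). The number of the nearest unshared OPC peak gave a rho of 0.120 with the OLG number, and permuting pairs within 10 bins of position gave at most 0.242 (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give, added after seeing the data).

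Sites in both lists were richer in promoters and in the repeat than sites in the OPC list alone. Promoters held 57.9% (51.5 to 64.0) of the 254 shared OPC peaks and 34.2% (32.8 to 35.6) of the 4389 OPC-only peaks, with an odds ratio of 2.65 (2.03 to 3.46, Fisher's exact test, two-sided p = 7.63e-14). The TCAT repeat was in 37.4% (31.4 to 43.7) of the shared and 10.8% (9.85 to 11.7) of the OPC-only peaks, with an odds ratio of 4.96 (3.73 to 6.55, Fisher's exact p = 1.15e-26). Stratified by quartile of the peak-name number, chosen after seeing the data, the odds ratio of the repeat was 2.53. Of the 100 OLG peaks with the repeat, 80 overlapped an OPC peak, against 174 of the other 1652 OLG peaks (odds ratio 33.8, 19.9 to 59.8, Fisher's exact test, two-sided p = 2.54e-53). The odds ratio of 33.8 was not stratified by the peak-name number. Low-numbered OLG peaks were richer both in the repeat and in shared sites than high-numbered ones. Neither a promoter nor the repeat was present in 55.6% of the OPC-only, 11.8% of the shared and 52.7% of the 1498 OLG-only peaks. Here shared sites were classed by their OPC peaks, so the 11.8% does not cover the OLG peaks of the shared sites.

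**Figure D2:**
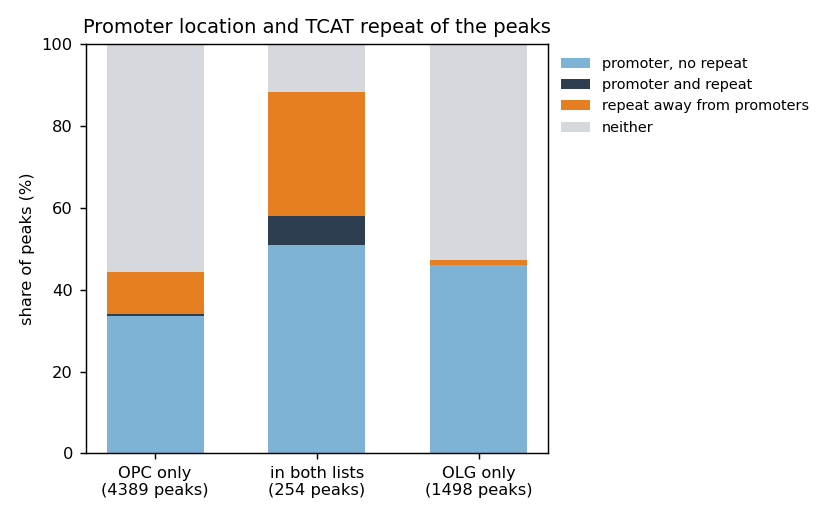
Share of peaks (vertical axis, %) by promoter location, within 1 kb of a protein-coding start, and by presence of a 12-base TCAT repeat, for OPC-only, shared and OLG-only peaks. Shared sites are classed by their OPC peaks. The repeat is in 37.4% of these shared OPC peaks, 10.8% of the OPC-only peaks and 1.34% of the OLG-only peaks.

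In the exact test at 10 kb without matching, genes that specify the oligodendrocyte lineage lay near ZFP24 peaks in OPC more often than other genes did. The trait was not particular to this list. Shares were similar for ribosomal and housekeeping genes (29.6%, odds ratio 2.88) and cytoskeleton genes (28.9%, 2.79), though not for myelin genes (12.5%, 0.977) or neuronal markers (8.33%, 0.621). Of 45 lineage regulators, 14, or 31.1%, had an OPC peak within 10 kb of a start site, against 12.8% of the 21644 genes with a protein-coding transcript (odds ratio 3.10, 1.52 to 6.01, Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.0143 over 28 tests). The peaks included those at Nfia, 207 bp downstream of the start, at Smarca4, the gene of the BRG1 chromatin remodeller, at 286 bp, at Zeb2 at 311 bp and at Olig1 at 380 bp. The call was lost in a permutation test with random lists matched on gene length (adjusted p = 0.0728) and on GC content around the start site (adjusted p = 0.505, chosen after seeing the data), and in the exact test with windows of 2 kb (adjusted p = 0.160) and 50 kb (adjusted p = 0.323). The 14 members compare with 5.74 expected without matching, 6.25 with length matching and 7.45 with GC matching, and the odds ratios at 2 kb and 50 kb were 2.47 and 1.61. The call was kept with each peak given to its nearest gene (odds ratio 4.33, Fisher's exact test, adjusted p = 3.52e-05) and with the lower-numbered peaks (3.43, 0.0177). The nearest-gene rule had no distance limit and no matching, and 7 lists passed with it in OPC. In OLG 6 of the 45 regulators had a peak (Fisher's exact test, adjusted p = 0.214), and the difference between the lists was not tested.

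Progenitor genes had peaks in OPC at Ptprz1, a receptor phosphatase gene, 341 bp upstream, at Olig1 and at Olig2. In all, 5 of 24 progenitor markers had a peak in OPC, among them Rlbp1, which was named only after its value was seen (Fisher's exact test, adjusted p = 0.442) and 0 of 24 in OLG (0.591). Among 40 myelin genes, 5 had an OPC peak, with those at Gpr37 at 163 bp and, with a TCAT repeat, in an intron of Mag at 6087 bp, and 4 had an OLG peak, including Tspan2 at 115 bp and Car2 at 255 bp (Fisher's exact test, adjusted p = 1 and 0.509). Among 40 genes of cholesterol and lipid synthesis, 5 had an OPC peak and 4 an OLG peak, and Cers2 had both (Fisher's exact test, adjusted p = 1 and 0.509).

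Growth factor signalling was the list that passed in OLG. Of its 40 genes, 9, or 22.5%, had an OLG peak, against 6.48% of the same 21644 genes (odds ratio 4.21, 1.76 to 9.09, Fisher's exact test, adjusted p = 0.0143). Members included Rictor, a subunit of the mTORC2 kinase complex, with its peak 139 bp from the start, Fgfr1 and Pik3r1 at 261 bp. The call was lost in a permutation test with lists matched on length (adjusted p = 0.0896) and on GC content (adjusted p = 0.505), and in the exact test on the lower-numbered peaks of each chromosome (adjusted p = 0.172, odds ratio 2.87). The 9 members compare with 2.59 expected without matching, 3.25 with length matching and 4.31 with GC matching. The call was kept in the exact test at 2 kb (odds ratio 5.25, adjusted p = 0.0108), at 50 kb (3.04, 0.0258) and with the nearest gene (6.01, 3.52e-05). None of these settings was matched, and with the nearest gene at any distance 3 lists passed in OLG. The lower-numbered peaks and the GC matching were chosen after seeing the data. In OPC 9 of the 40 genes had a peak (0.253), among them Tsc1 and Rptor.

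The other 9 lists did not pass Fisher's exact test after adjustment in either cell type. In OPC, peaks lay near 11 of 38 cytoskeleton genes (exact test, adjusted p = 0.0594), and near 11 of 42 cell cycle genes such as Cdk1, Rbl2 and Aurkb, 12 of 46 genes of the Notch, Wnt and BMP pathways such as Notch2, Bmp2 and Id4, 11 of 41 chromatin genes and 8 of 27 ribosomal and housekeeping genes (0.0690 for each of these 4). In OLG, the counts for the same 5 lists were 3 (0.926), 5 (0.442), 5 (0.442), 2 (1) and 5 (0.0970). For markers of other brain cells the shares are set against 12.8% of these genes in OPC and 6.48% in OLG. Neuronal markers had 2 of 24 in OPC (8.33%) and 3 of 24 in OLG (12.5%; adjusted p = 0.926 and 0.442 in the exact test). Astrocyte markers had 2 of 17 in each (11.8%; 1 and 0.509), microglial markers 1 and 2 of 16 (6.25% and 12.5%; 0.926 and 0.509) and vascular markers 1 of 18 in each (5.56%; 0.926 and 1).

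**Figure D3:**
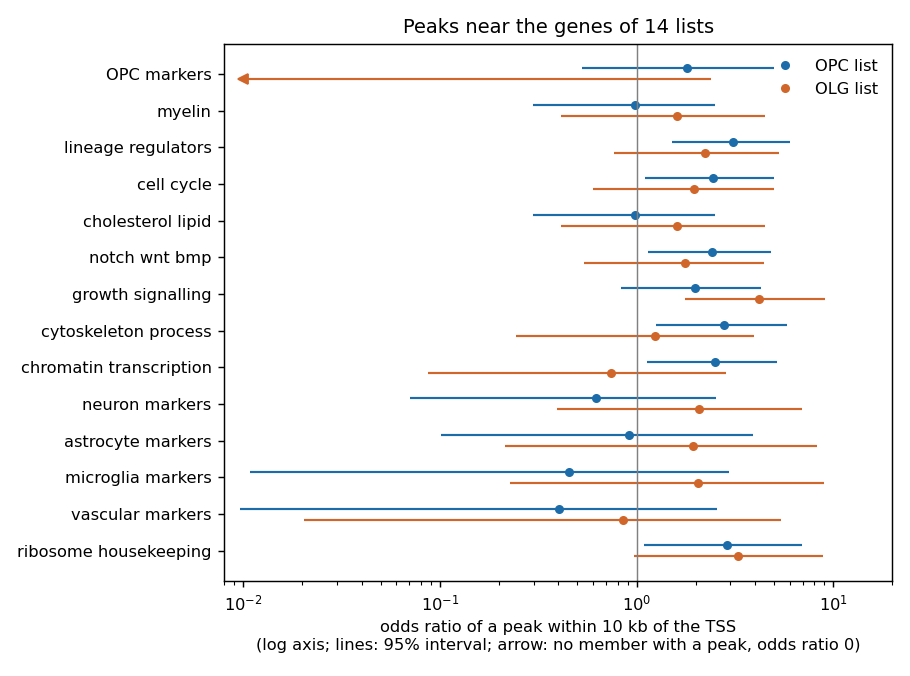
Odds ratio of having a peak within 10 kb of a start site (horizontal log axis) for the genes of 14 lists (rows) against all other protein-coding genes, for the OPC and the OLG list, with 95% intervals as lines. Lineage regulators in OPC are at 3.10 and growth signalling in OLG at 4.21, and the arrow marks 0 of 24 progenitor markers in OLG.

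In all, 2761 genes had an OPC peak within 10 kb and 1402 an OLG peak, with 458 in both sets against 178.8 from independent sets of these sizes (odds ratio 3.78, 3.34 to 4.27, Fisher's exact test over genes, p = 8.63e-91). Genes are not independent replicates. The expected number gives each gene the same chance of a peak, and it was not matched on GC content or gene length. Both lists favoured promoters, so the excess is not corrected for a preference that they have in common.

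The lineage factors Olig1, Olig2 and Sox10 each had an OPC peak within 10 kb and no OLG peak within 10 kb. The Olig1 peak (chromosome 16, 91270048 to 91270256, GRCm38) lay in the coding exon, and the Olig2 peak (chromosome 16, 91220072 to 91220280) was intergenic, 5281 bp upstream. Neither held the repeat. The Sox10 peak (chromosome 15, 79171852 to 79172060) was 6716 bp upstream, in an intron of a non-coding gene, and held a TCAT tract of 12 bases (79171956 to 79171967), with another of 15 bases just outside it (79171834 to 79171848). A site shared by both lists lay further upstream, where the OLG peak (chromosome 15, 79202058 to 79202278) was 36928 bp from the Sox10 start site and held a 36-base tract. The protein-coding start nearest to that OLG peak was that of Pick1, at 27005 bp. None of Zfp24, Mbp, Mog, Cnp, Pdgfra, Cspg4 and Myrf had a peak within 10 kb in either list. The closest were an OLG peak 11830 bp upstream of Cspg4, a proteoglycan gene of progenitors, and an OPC peak 19870 bp downstream of the Mog start site. Mbp, which encodes myelin basic protein, had its nearest OPC peak at 183591 bp and its nearest OLG peak at 1488833 bp. For Zfp24 itself the distances were 184531 bp and 65226 bp. The presence of a peak in a single list was not tested against the other list at any single gene.

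**Figure D4:**
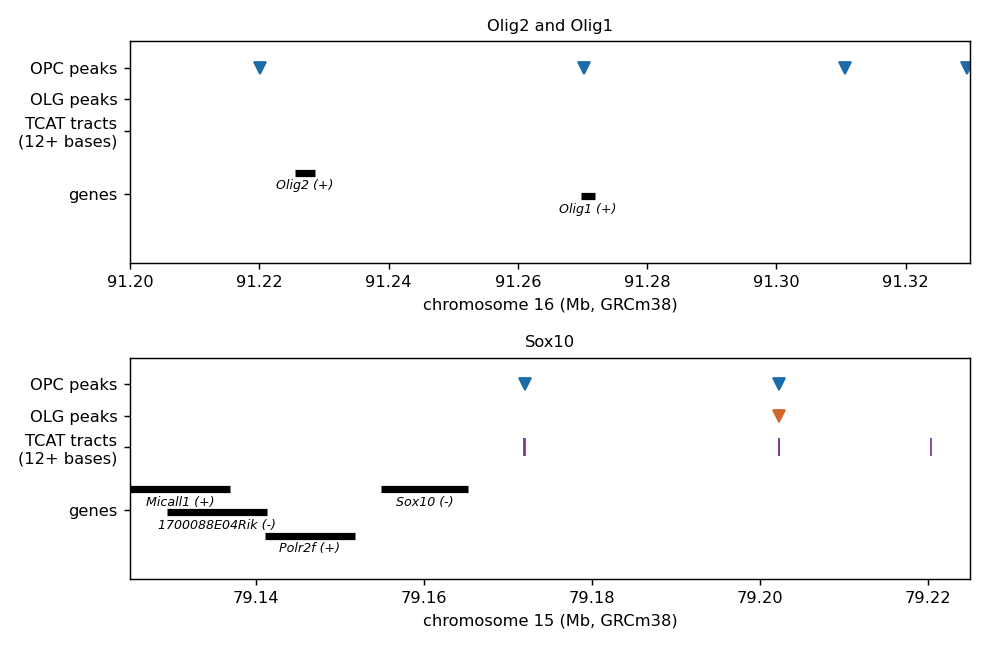
Positions of OPC peaks, OLG peaks and TCAT tracts of 12 bases or more around Olig2 and Olig1 (upper panel, chromosome 16) and Sox10 (lower panel, chromosome 15), with the horizontal axis in Mb of GRCm38 and genes as bars with their strand. The shared site upstream of Sox10, which lies nearer to the start of Pick1, carries both a peak of each list and a tract. The Olig1 and Olig2 windows show OPC peaks only.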

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

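The test of the lowest-numbered OLG peaks, that of the repeat at OLG promoters and the comparisons with peaks matched on GC content were chosen after the results they bear on had been seen. The OPC and OLG lists differed in their share of promoter peaks, 35.5% against 47.8%, an odds ratio of 0.599 (0.535 to 0.671, Fisher's exact test, two-sided p = 2.39e-19). They also differed in their share of peaks with a TCAT repeat, 12.2% against 5.71%, an odds ratio of 2.30 (1.84 to 2.89, p = 1.80e-15 in the exact test). Without the shared peaks these odds ratios were 0.607 (0.538 to 0.686) and 8.90 (5.67 to 14.8). Leaving out the shared peaks took away 80 of the 100 OLG repeat peaks and 95 of the 567 OPC repeat peaks. The rise to 8.90 reflects that uneven removal. Cell type, library and calling changed together between the lists, so the difference has no replicate check.

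Few OPC and OLG peaks coincided, although ZFP24 was the target in both. The tables argue against all OLG-only peaks being background calls, since 1.34% of them (0.817 to 2.05) held the repeat against 0.0668% of their flanks. That leaves background open for most of the OLG-only peaks without the repeat. Weak peaks that miss the threshold of the other list stay open as a partial account. By name number, the share of OLG peaks in the OPC list was 52.1% (44.2 to 59.9) of the 167 in the lowest 10% on each chromosome. It fell to 4.30% in the highest 10%, and for OPC peaks in the OLG list the share fell from 24.2% to 2.11%. Such a fall is what a threshold would give if that number is a rank. A threshold alone was also expected to leave nearly all of the lowest-numbered OLG peaks in the longer OPC list, which was not seen. A difference in depth or antibody yield between the libraries, and a change of ZFP24 sites with differentiation, both stay open and may act together.

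Promoter peaks lay in GC-rich sequence. GC content alone is an unlikely full account, because the OPC promoter share was 2.33-fold that of positions matched on GC content, and in OLG 1.70-fold. The repeat is also an unlikely general cause of promoter peaks in OPC, where it was rarer at promoters than elsewhere, with an odds ratio of 0.123 (0.0873 to 0.170). It may still account for some of them, since 42 OPC promoter peaks held it. In OLG the odds ratio was 0.307 with a lower end of 0.182. Its upper end lay just above the bound of 0.5 that OPC met, so that bound did not decide. Still, 815 of the 838 OLG promoter peaks lacked the repeat, which argues against it as a general cause there. The repeat may account for some of the 23 OLG promoter peaks that held it. Open chromatin at active promoters, which can raise ChIP signal without binding, was not measured here and stays open.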

How the results depend on the processing

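Settings that use the peak-name number or GC matching, the class-wise moves, the mismatch and left-flank settings and the 50 bp pairs were chosen after seeing the data. No paired analysis was possible because each group had 1 library, and no library could be left out. The settings by peak value were not run, since the lists hold none. Direction and side of the threshold were kept by overlap (174 to 380 peaks), promoter share (26.8% to 44.7% in OPC, 36.6% to 60.2% in OLG), repeat share (10.3% to 20.5% and 4.45% to 9.53%), and the contrast of shared with OPC-only peaks (odds ratios 1.96 to 2.90 and 2.53 to 4.96). The rank correlation was 0.720 for pairs with centres within 50 bp.

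By construction, the lower-numbered peaks were 2316 in OPC and 871 in OLG. The number of gene lists that passed, 1 in each cell type, was 7 in OPC and 3 in OLG with each peak given to its nearest gene at any distance, and 0 in both with lists matched on gene length or on GC content. It was 3 in OPC with lower-numbered peaks. The list that passed was not always the same. In OPC it was the cytoskeleton list at 2 kb and the cell cycle list at 50 kb, and in OLG the ribosomal list with lower-numbered peaks. With lower-numbered OPC peaks the lineage, cytoskeleton and Notch, Wnt and BMP lists passed. With the nearest gene, OPC passed Fisher's exact test for Notch, Wnt and BMP (27 of 46, odds ratio 7.04, adjusted p = 5.23e-09), lineage regulators (4.33), progenitor markers (11 of 24, 4.18, 0.00421), growth, chromatin, cytoskeleton and cell cycle, and OLG for growth (6.01), lineage (12 of 45, 4.54, 0.000567) and Notch, Wnt and BMP (3.92). The cause was not tested.

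Over single lists and settings, 128 calls were unchanged, 7 were lost and 13 gained. A further 20 ratios changed side of 1 without passing the test in either setting. At 2 kb this was vascular markers in OLG (1.23). At 50 kb these were, in OLG, progenitor markers (1.12), lipid genes (0.992), astrocyte (0.750) and microglial markers (0.803), and in OPC myelin genes (1.79), neuronal (1.21) and astrocyte markers (1.32). With the nearest gene they were, in OLG, progenitor (1.13), astrocyte (0.775) and microglial markers (0.827), and in OPC myelin genes (1.64) and astrocyte markers (2.69). With GC matching it was the OLG cytoskeleton list (0.786, a ratio of counts with 0.5 added, where the others are odds ratios). With lower-numbered peaks they were, in OLG, the cytoskeleton (0) and vascular lists (1.51), and in OPC myelin (1.33), lipid (1.71), neuronal (1.09) and astrocyte lists (1.60). The cause was not tested. Unknown depth and 1 library per group limit all results.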

Other observations

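The ranking of shared sites, the counts by name number and the control motif below were chosen after the values had been seen. Name numbers were ranked within each chromosome and the rank was divided by the number of peaks on it, which favours chromosomes with many peaks. The 10 shared sites with the lowest mean of this fraction over both lists were named by their nearest protein-coding start. These were the starts of Celf1, Rasgef1c, Vgf, Sdc3, Kcnj10, Zfp668, Ahi1, Cryaa, Slc17a3 and Scnn1a. The OPC peak centre was 88756 bp from the start of Cryaa, 36772 bp from Rasgef1c and 12044 bp from Sdc3, and within 10 kb of the others. Of the 10 sites, that at Zfp668 was a promoter peak without the repeat, and the other 9 had the repeat in OPC. The tract was 57 bases long in an intron of Kcnj10 (chromosome 1, 172351133 to 172351189), the gene of a glial potassium channel. It was 53 bases long in an intron of Scnn1a and 50 bases long by Celf1, an RNA-binding protein gene, 324 bp from its start site. Among OPC peaks in the lowest 10% of numbers on each chromosome 48.4% held the repeat, against 3.80% in the highest 10%, and for OLG peaks the shares were 28.7% and 2.69%.

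The X chromosome held few peaks. In OPC it had 32, or 0.187 per Mb against 1.87 per Mb on the autosomes, where chromosome 1 was lowest at 1.45, and in OLG it had 11, or 0.0643 per Mb against 0.707. A lack of promoters and TCAT tracts on X is an unlikely account, since the odds ratio of a promoter peak for X-linked against autosomal genes in OPC was 0.173 (0.0960 to 0.287), and for tracts of 16 bases or more 0.201 (0.0645 to 0.479). A single X copy in male cells cannot be told apart from other causes, because the ratio for tracts of 24 bases or more was 0.304 (0.128 to 0.722), with 137 such tracts on X, and the sex of the animals is not given in the labels. Filtering of X-linked reads before deposit was not tested, and no biological explanation was tested either.

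Of the OPC peaks, 2472 had neither a promoter nor the repeat, and it was asked whether they hold other motifs or a degenerate repeat. A hypothesis that they are lineage enhancers with SOX, E-box or NFI motifs stayed open. Of these 3 motifs the highest ratio to flanks was that of the E-box CAGCTG at 1.34 (1.13 to 1.58, exact McNemar test, adjusted p = 0.00737 over the 12 motifs tested), on which the bound of 1.5 set beforehand fell within the interval. Reading the interval in this way was decided after the value was seen, and by the point value alone the bound was not reached. A control of the same base composition, CTGCAG, had a ratio of 1.42 (1.21 to 1.66), so that base composition may account for the E-box excess. The SOX motif had a ratio of 0.985, and the NFI motif was in 0 peaks and 0 flanks, which tests nothing. Among the other 9 motifs, outside the hypothesis, CTCF was in 15 peaks and 3 flanks, a ratio of 5.00 (1.45 to 17.3, exact McNemar test, adjusted p = 0.0452), and CRE was in 8 peaks and 1 flank, or 0.324% against 0.0405% (interval of the ratio 1.00 to 64.0, exact McNemar test, adjusted p = 0.156). A TCAT repeat with up to 2 mismatches in 12 bases was in 7.69% of these peaks and 6.47% of flanks, a ratio of 1.19 (0.969 to 1.45, exact McNemar test, two-sided p = 0.108), which argues against an interrupted repeat as a common feature at a ratio of 1.5. In the corresponding 837 OLG peaks the E-box had a ratio of 2.10 (1.57 to 2.81) and the control 1.46 (1.14 to 1.88), and CTCF was in 5 peaks and 2 flanks, comparisons outside the hypothesis.

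That tandem tetranucleotides in general would be at peaks as often as TCAT had also been set out before its result was seen. Of tracts of 16 bases or more, 8.04% (7.39 to 8.72) of the TCAT class and 2.17% (0.451 to 6.22) of the next class, AACG, were at an OPC peak. In OLG the shares were 1.28% (1.03 to 1.59) and 0.725% (0.0183 to 3.97), so TCAT and AACG, with its 138 tracts, were not told apart there. Classes with many more tracts were lower in OLG, such as TCAC at 0.177% (0.0215 to 0.638) and AAAC at 0.00616% (0.00200 to 0.0144). These values argue against tandem tetranucleotides in general being at OLG peaks as often as TCAT. Other classes with few tracts were not told apart from TCAT either.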
